A study of Arabidopsis thaliana with 6 samples.

How the data were processed

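Polyadenylated RNA was sequenced from Col-0 and Can-0 seedlings, roots and stage 12 floral buds, with 1 library for each accession and tissue. Libraries were made by adapting an Illumina small RNA protocol to fragmented mRNA, per the labels' protocols. The run and lane codes in the labels place both seedling libraries in run 33 (Col-0 in lane 2, Can-0 in lane 1) and both root libraries in run 40 (lanes 3 and 2), while the floral bud libraries came from run 36 for Col-0 and run 35 for Can-0. Tissue is thus confounded with run, and root also with growth on plates.

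The deposited files give RPKM, reads scaled to gene model length and to mapped reads, as computed by the authors per the file headers. Builds TAIR9 and TAIR10 are named without a role per the submitters' processing notes. The aligner, the counting program, the treatment of reads that match several genes, the use of strand and the depth are not given in the sources used here. Many of the small values in each library lie on multiples of what 1 read is worth, and the mapped reads per library were estimated from that step. Of 6211 genes with a single annotated transcript and a value of 20 reads or fewer in some library, 2747 had only values within 0.1 of a whole number of reads. The most frequent Col-0 over Can-0 ratio of small RPKM values, which is the inverse of the ratio of depths, was 0.963 in seedling, 1.01 in root and 0.969 in floral bud. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

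All computation started from these RPKM values. The RefSeq annotation of assembly TAIR10.1 was used only for symbols, for which genes neighbour each other, for transcript lengths and for transcript similarity, since the build behind the values is not settled. Of 28775 feature identifiers 28009 matched it and 766 did not. Genes with another transcript at 95% identity or more over at least 50% of their length by BLAST+ 2.17.0 are named as having a near-identical copy, since their reads may have been shared.

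Tissues and accessions were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with tissue and accession as terms, an empirical Bayes trend, and a two-sided test at a Benjamini-Hochberg adjusted p under 0.05. The 20830 genes with at least 1 RPKM in at least 2 of the 6 libraries were tested. With 1 library per group the spread was estimated from how far the tissue differences differ between the accessions, on 2 residual degrees of freedom moderated by 2.55 prior degrees of freedom. A call on tissue is therefore a mean difference over these accessions that is large against how far they differ, and a call on accession a mean difference over the 3 tissues that is large against how far those differ. A list called between accessions can still go the other way in 1 tissue. A gene was called enriched in a tissue where it passed against both others with a difference of at least 2. Within a tissue no test was made. Genes with at least 1 RPKM in either library and a difference of at least 2 were counted instead.

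A set of 26 gene lists with 443 members, written with the comparisons, filters and naming rule before the data were examined, covered photosystem, carbon fixation, photorespiration, root ion transport, root hair, endodermis and suberin, root meristem, floral organ identity, anther tapetum, pollen, meiosis, cell division, aliphatic and indole glucosinolates, glucosinolate breakdown, flowering time, NLR immune receptors, salicylic acid defence, jasmonate, heat shock, cold and osmotic response, morning and evening clock, iron deficiency, flavonoid and anthocyanin, and reference genes. IRT1 and its partner FRO2 are in both the ion transport and the iron deficiency lists. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within each comparison, and each gene was also adjusted over the list alone. The estimated correlation rests on 2 residual degrees of freedom, so a list that it does not call is not thereby shown to be unchanged. Within a tissue a list's median was placed among 10000 random lists of the same size matched on mean expression. A further 5 lists, of dawn-phased, dusk-phased, light response, root triterpene and camalexin genes, were written after the tests had been seen, the last pair around genes already named. AOP2 was not analysed here.

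The named genes are the 10 genes enriched in each tissue with the highest smaller difference, the 10 higher and 10 lower genes with the largest accession difference, the 5 highest and 5 lowest within each tissue, and of each list up to 4 members with the largest difference plus members past the threshold in the opposite direction. FLC, FRI, AOP3, MAM1, MAM3, ESP and GS-OH were named in the accession comparison whatever their values. Alternatives were the pseudocount, the filter, the scaling, the empirical Bayes settings, a minimum difference, the terms of the model, and leaving out each library or each tissue's pair, and voom on approximate reads was added after the results were seen. On simulated data with 200 of 20830 genes changed, the accession test recovered 60%, 95.5% and 100% of changes of 2-, 4- and 8-fold with 10, 19 and 10 false calls, and the seedling against root test 0%, 92.5% and 99% with 0, 23 and 16. In the data 12398 genes passed between seedling and root, so the adjusted threshold was stricter in the simulation. Its noise was drawn independently for each gene and library. These recoveries therefore do not carry over to the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, random lists and plots.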

Results

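The libraries held polyadenylated RNA of Arabidopsis thaliana from Col-0, the accession whose genome is the reference, and Can-0, an accession from the Canary Islands. Both are founders of MAGIC, a population of inbred lines bred from several intercrossed accessions. Seedlings were taken at 11 days from soil, roots at 10 days from plates and floral buds at stage 12 from soil. All grew under 16 hours of light and 8 of dark at 20 C. Each accession and tissue had 1 library, 6 libraries in all, so no group had a replicate. The comparisons address which transcripts differed among the tissues over both accessions and which differed between the accessions over the tissues. Values are RPKM (reads scaled to gene model length and to mapped reads) deposited by the authors for 28775 features. Differences are on the log2(RPKM + 1) scale throughout, so where a tissue or an accession was near 0 they depend on the 1 that was added and are not folds. A pair of RPKM values gives Col-0 and then Can-0.

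All 6 libraries were sequenced to a like depth. The step between neighbouring small values put the mapped reads, in units of 1e6, at 22.6, 22.6 and 22.8 in Col-0 seedling, root and floral bud, and at 21.8, 22.9 and 22.1 in Can-0. A single read in a gene of 1 kb then equalled 0.0437 to 0.0459 RPKM, and a gene of 1 kb listed at 0 was limited to 0.131 to 0.138 RPKM by the 3 reads that a count of 0 allows, for counting error only. Between 17222 and 18989 features reached 1 RPKM. Chloroplast genes made up 6.37% and 6.60% of the RPKM total in seedling, 0.348% and 0.394% in root and 1.86% and 2.31% in floral bud. AT2G01021, an rRNA-derived feature, ranged from 4584 to 14856 RPKM. Across genes, which are not independent replicates, log2(RPKM + 1) correlated at r = 0.955 to 0.962 between the accessions within a tissue and at 0.483 to 0.764 between tissues. Principal components 1, 2 and 3 held 61.8%, 30.4% and 4.98% of the variance, and component 3 separated Col-0 from Can-0.

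Seedlings differed from roots first in the photosynthetic machinery. All 37 photosystem and antenna genes, which capture light, and all 19 carbon fixation genes were higher in seedling, by medians of 7.63 and 8.11. RBCS3B (AT5G38410), a small subunit of the CO2-fixing enzyme Rubisco, stood at 4472 and 3568 RPKM in seedling and 0.309 and 0.0437 in root (11.74 ± 0.11, adjusted p = 8.78e-05). The antenna gene LHCB1.4 (AT2G34430) stood at 1269 and 870.3 RPKM and 0.0438 and 0 (10.01 ± 0.17, adjusted p = 8.78e-05). Of 13 photorespiration genes, which salvage the product of Rubisco's reaction with oxygen, 12 were higher in seedling (median 3.98), among them GOX1 (AT3G14420), a glycolate oxidase, at 451 and 352 against 0.401 and 0.223 RPKM (8.25 ± 0.11, adjusted p = 8.78e-05). Against all other genes, limma's camera gave the photosystem list adjusted p = 1.82e-27, carbon fixation adjusted p = 2.59e-16 and photorespiration adjusted p = 7.84e-10, and each had adjusted p = 0.376 with an estimated correlation. With the adjustment over each list alone, 37, 19 and 12 members passed. RBCS3B and RBCS2B (AT5G38420) are near-identical copies, as are LHCB1.1 (AT1G29920), LHCB1.2 (AT1G29910) and LHCB1.3 (AT1G29930), so how reads were divided within each family is uncertain.

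Roots carried more transcript for mineral uptake and for their own cell types. Of 20 tested ion transport genes, 18 were lower in seedling than root (median -3.62), including the ammonium transporter AMT1;3 (AT3G24300) (-6.43, adjusted p = 9.38e-05), the sulfate transporter SULTR1;2 (AT1G78000) (-6.33, adjusted p = 0.000214) and the iron transporter IRT1 (AT4G19690) (-5.83, adjusted p = 0.000214). The phosphate transporter PHT1;1 (AT5G43350) (-6.71, adjusted p = 9.10e-05), which has a near-identical copy, was lower as well. Of 18 iron deficiency genes, 14 were lower in seedling (median -3.29), as in NAS2 (AT5G56080) (-6.35, adjusted p = 0.000124), which makes the metal chelator nicotianamine. The iron-transporting OPT3 (AT4G16370) (1.11, adjusted p = 0.0164, and 0.0532 to 0.0723 without 1 of Can-0 root, Col-0 root and Col-0 seedling) was higher. All 11 root hair genes were lower (median -2.90), with the cell-wall protein gene PRP3 (AT3G62680) (-5.16, adjusted p = 0.000176) at 0 and 0.0391 against 43.2 and 29.0 RPKM. So were 15 of 16 genes of the endodermis and its suberin coat (median -4.63), such as CASP1 (AT2G36100) (-5.79, adjusted p = 9.81e-05) of the Casparian strip and the suberin hydroxylase CYP86A1 (AT5G58860) (-5.90, adjusted p = 0.000132). All 6 root meristem genes were lower in seedling (median -1.82), with the auxin exporter PIN2 (AT5G57090) (-5.03, adjusted p = 0.000143) and the stem-cell regulator PLT2 (AT1G51190) (-2.58, adjusted p = 0.000591). Camera gave ion transport adjusted p = 1.57e-05, iron deficiency 0.0116, root hair 0.000809, endodermis 5.21e-06 and meristem 0.0126, and in that order adjusted p = 0.376, 0.576, 0.576, 0.376 and 0.405 with an estimated correlation. Adjusted over the list alone, 19, 15, 11, 16 and 6 members passed. The root triterpene genes MRN1 (AT5G42600) and CYP71A16 (AT5G42590) stood at 34.7 and 74.1 and at 52.7 and 116 RPKM in root. Both were listed at 0 in both seedlings, while CYP705A1 (AT4G15330) stood at 0 and 3.05 RPKM in seedling. With PRP3 near 0 there too, the seedling libraries may have held little root RNA. Growth in soil against plates could not be told apart from that.

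Defence chemistry divided between the tissues. Glucosinolates are sulfur compounds that myrosinases turn into toxins when tissue is wounded. Of 20 genes for the aliphatic kind, 9 were higher in seedling and 4 higher in root (median 0.96). CYP79F1 (AT1G16410) was higher in seedling (7.60 ± 0.45, adjusted p = 0.000364) and its paralog CYP79F2 (AT1G16400) higher in root (-2.65 ± 0.20, adjusted p = 0.000659). The regulator MYB29 (AT5G07690) (5.67, adjusted p = 9.81e-05) and the chain-elongation gene MAM1 (AT5G23010) (4.07, adjusted p = 0.00926) were higher in seedling. FMOGS-OX4 (AT1G62570) (-4.53, adjusted p = 0.000359), FMOGS-OX5 (AT1G12140) (-1.09, adjusted p = 0.00161) and MAM3 (AT5G23020) (-2.67, adjusted p = 0.0344, and 0.0849 to 0.109 without 1 of Can-0 root, Col-0 root and Col-0 seedling) were higher in root. Of 13 genes for the indole kind, 8 were lower in seedling (median -1.28), including CYP81F4 (AT4G37410) (-4.3, adjusted p = 0.00187) and the regulator MYB34 (AT5G60890) (-2.54, adjusted p = 0.000381). The related MYB51 (AT1G18570) (1.31, adjusted p = 0.0134, and 0.0559 to 0.0656 without 1 of Can-0 root and Can-0 seedling) was higher. The myrosinase TGG1 (AT5G26000) stood at 841 and 974 RPKM in seedling and 0 and 0.0237 in root (9.81, adjusted p = 8.78e-05). NSP1 (AT3G16400) (-3.95, adjusted p = 9.10e-05), which diverts breakdown products to nitriles and has a near-identical copy, was higher in root. So was its relative NSP5 (AT5G48180) (-1.79, adjusted p = 0.0217, and 0.0554 to 0.0752 without 1 of Can-0 root, Can-0 seedling and Col-0 seedling). The breakdown gene ESP (AT1G54040) (7.13, adjusted p = 0.0255, and 0.0975 without Can-0 seedling) was higher in seedling. Camera gave the aliphatic list adjusted p = 0.00545, adjusted p = 0.576 with an estimated correlation, and did not call the indole list (adjusted p = 0.125) or the 6 breakdown genes (adjusted p = 0.159). Adjusted over the list alone, 13, 10 and 5 members passed.

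Salicylic acid, jasmonate and NLR genes passed more often upward than downward in seedling. Of 19 genes of the salicylic acid response against pathogens, 11 were higher (median 1.91), among them PR1 (AT2G14610) at 72.7 and 248 RPKM and listed at 0 in both roots (7.08, adjusted p = 0.000430) and PCC1 (AT3G22231) (7.85, adjusted p = 0.00181). PAD4 (AT3G52430) (-0.73, adjusted p = 0.0129, and 0.0547 to 0.0830 without 1 of Can-0 seedling, Col-0 root and Col-0 seedling) and GRXC9 (AT1G28480) (-1.62, adjusted p = 0.0439, and 0.0744 to 0.161 without 1 of Can-0 floral bud, Col-0 floral bud, Col-0 root and Col-0 seedling) were higher in root. Of 15 genes of the wound hormone jasmonate, 8 were higher in seedling and none passed in the other direction (median 1.22), with the lipoxygenase LOX2 (AT3G45140) (8.87, adjusted p = 0.000289) and JAZ9 (AT1G70700) (4.93, adjusted p = 8.78e-05). Of 28 NLR receptors, which recognise pathogen effectors, 15 were higher (median 0.69), including RPP7 (AT1G58602) (4.05, adjusted p = 0.00185) and RPP13 (AT3G46530) (3.22, adjusted p = 0.000355). In contrast, NRG1.2 (AT5G66910) (-0.78, adjusted p = 0.00681), ADR1 (AT1G33560) (-1.04, adjusted p = 0.00796, and 0.0518 without Col-0 root) and ADR1-L2 (AT5G04720) (-0.76, adjusted p = 0.0245, and 0.0528 to 0.128 without 1 of Can-0 root, Col-0 root and Col-0 seedling) were higher in root. Camera gave salicylic acid adjusted p = 0.000595, jasmonate adjusted p = 0.00154 and NLR adjusted p = 0.000199, and in that order adjusted p = 0.576, 0.576 and 0.376 with an estimated correlation. Adjusted over the list alone, 13, 7 and 18 members passed.

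Flowering time and pigment genes went both ways between seedling and root. SNZ (AT2G39250), an AP2-like repressor, stood at 59.9 and 62.4 RPKM in seedling and 0.142 and 0.140 in root (5.77, adjusted p = 9.10e-05), and the MADS-box repressor SVP (AT2G22540) (3.03, adjusted p = 0.00178) was higher too. Of 21 flowering time genes, 7 were higher in seedling and 4 higher in root (median 0.70; camera adjusted p = 0.0116, adjusted p = 0.515 with an estimated correlation). Those higher in root were MAF2 (AT5G65050) (-0.78, adjusted p = 0.00344), FD (AT4G35900) (-1.08, adjusted p = 0.00847, and 0.0560 to 0.0719 without 1 of Can-0 seedling and Col-0 root), SMZ (AT3G54990) (-0.87, adjusted p = 0.0135, and 0.0703 to 0.0820 without 1 of Can-0 seedling and Col-0 root) and FRI (AT4G00650) (-0.67, adjusted p = 0.0246, and 0.0764 to 0.137 without 1 of Can-0 root, Can-0 seedling, Col-0 root and Col-0 seedling). Anthocyanin genes such as LDOX (AT4G22880) (4.75, adjusted p = 0.00238) and DFR (AT5G42800) (4.37, adjusted p = 0.00204) were higher in seedling. The flavonol regulator MYB12 (AT2G47460) (-4.35, adjusted p = 0.00208) and the earlier enzymes F3'H (AT5G07990) (-1.97, adjusted p = 0.0277, and 0.0682 to 0.103 without 1 of Can-0 seedling, Col-0 root and Col-0 seedling) and F3H (AT3G51240) (-1.80, adjusted p = 0.0430, and 0.0868 to 0.144 without 1 of Can-0 seedling, Col-0 root and Col-0 seedling) were higher in root. That list's median was 0.77 (camera adjusted p = 0.0126, adjusted p = 0.576 with an estimated correlation), but -1.19 when only genes with a mean of at least 5 RPKM were tested. Among clock genes that peak in the morning PRR7 (AT5G02810) (1.76, adjusted p = 0.00273) was higher in seedling (list median 1.11; camera adjusted p = 0.0346, adjusted p = 0.576 with an estimated correlation). Of 9 that peak in the evening 2 were lower (median -1.0; camera adjusted p = 0.727). Adjusted over the list alone, 9 flowering time, 12 flavonoid, 1 morning and 1 evening genes passed.

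Most lists of stress, growth and reproduction were not called between seedling and root. Of 8 tested heat shock genes 6 were lower in seedling (median -1.13), with HSP17.6B (AT2G29500) (-4.45, adjusted p = 0.00120) and HSP70 (AT3G12580) (-3.06, adjusted p = 0.00236). HSP15.7 (AT5G37670) (0.96, adjusted p = 0.00911, and 0.0568 to 0.0805 without 1 of Can-0 root, Can-0 seedling and Col-0 root) was higher. The freezing-protective COR15A (AT2G42540) (5.37, adjusted p = 0.00402) and COR15B (AT2G42530) (6.19, adjusted p = 0.00222) were higher in seedling. The dehydrins COR47 (AT1G20440) (-2.84, adjusted p = 0.00496), ERD10 (AT1G20450) (-1.93, adjusted p = 0.00228) and LTI30 (AT3G50970) (-5.05, adjusted p = 0.00512) were higher in root, around a median of 0.16 (0.43 median-centred) over 12 cold and osmotic genes. Of 15 cell division genes 8 were lower in seedling (median -0.56, or 5 and -0.29 with median-centred values), as in the mitotic kinase CDKB1;1 (AT3G54180) (-1.30, adjusted p = 0.00279). Among 10 tested meiosis genes, 3 were lower (median -0.54, or -0.26 median-centred and -0.10 with quantile normalization), including ASY1 (AT1G67370) (-1.91, adjusted p = 0.00179) of the chromosome axis. Of 18 floral organ genes 2 were higher and 2 lower (median 0.03, or 0.30 median-centred), with SEP3 (AT1G24260) (1.58, adjusted p = 0.000897) and AP2 (AT4G36920) (-1.75, adjusted p = 0.00249). Medians of the pollen list, 0.00 (0.27 median-centred), and of the tapetum list, -0.03 (0.24 with median-centred values), lay near 0, while camera ranked both upward without a call (adjusted p = 0.294 and 0.815). None of the other lists here was called either, with camera adjusted p = 0.167 for heat shock, 0.378 for cold, 0.260 for cell division, 0.294 for meiosis and 0.294 for floral organs. The 11 genes often used as references were not level: 9 were lower in seedling (median -0.68, or 4 and -0.41 with median-centred values; camera adjusted p = 0.0390, adjusted p = 0.576 with an estimated correlation), as in ACT8 (AT1G49240) (-2.36, adjusted p = 0.000838) and GAPC1 (AT3G04120) (-1.84, adjusted p = 0.000801).

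By limma, 12398 of 20830 tested genes differed between seedling and root at a Benjamini-Hochberg adjusted p under 0.05 in a test that used the accessions in place of replicates, 3849 higher and 8549 lower in seedling, and 7856 of them by at least 1. Without Col-0 root, 8068 differed. The median over all tested genes was -0.33, a shift of the whole scale that quantile normalization moved by 0.25 to -0.08 and median-centring by 0.27 to -0.06, with 4851 higher and 6430 lower under the first and 4818 and 6135 under the second. Tissue could not be separated from sequencing run, nor root from growth on plates.

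Floral buds against seedlings showed the genes that build flowers and pollen. AP3 (AT3G54340), PI (AT5G20240) and AP1 (AT1G69120), MADS-box genes that specify petals, stamens and sepals, were higher in bud by 7.76 ± 0.14, adjusted p = 0.000117, 7.16 ± 0.43, adjusted p = 0.000792 and 6.84 ± 0.15, adjusted p = 0.000117. AP3 stood at 0.0852 and 0.133 RPKM in seedling and 219.5 and 262 in floral bud. Of 18 floral organ genes 17 were higher (median 4.90; camera adjusted p = 1.07e-08, adjusted p = 0.467 with an estimated correlation; 18 adjusted over the list alone). All 20 tested of 24 listed pollen genes were higher (median 5.56; camera adjusted p = 4.05e-11, adjusted p = 0.467 with an estimated correlation; 20 adjusted over the list alone). The pectin methylesterase VGD1 (AT2G47040), which acts in the growing pollen tube, was listed at 0 in both seedlings and stood at 465 and 593 RPKM in bud (9.04, adjusted p = 0.000117). The tapetum is the anther layer that feeds and coats pollen. Of its 27 listed genes 13 were tested, and 10 of these were higher (median 3.16; camera adjusted p = 0.00116, adjusted p = 0.473 with an estimated correlation; 10 adjusted over the list alone). The pollen-coat protein gene GRP17 (AT5G07530) stood at 323 and 786 RPKM (8.98, adjusted p = 0.000336). Members of the pollen and tapetum lists that reach 1 RPKM in bud alone entered the test only by being high there. The filter thus favours a higher value in bud, and the tested members do not speak for the whole lists. Meiosis genes were not called as a list: their median of 0.24 turned to -0.47 with quantile normalization, camera gave adjusted p = 0.743, and MSH5 (AT3G20475) (0.65, adjusted p = 0.0321, and 0.0954 to 0.223 without any 1 of the 6 libraries) turned to -0.09 with quantile normalization.

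Photosynthetic and glucosinolate genes were mostly lower in bud than in seedling. Of 37 photosystem genes 35 were lower in bud (median -2.13, or 25 and -1.29 with quantile normalization), led by LHCB1.4 at 8.73 and 5.65 RPKM (-7.03 ± 0.17, adjusted p = 0.000117). The minor antenna gene LHCB4.3 (AT2G40100) (1.34, adjusted p = 0.0295, and 0.104 to 0.171 without 1 of Can-0 floral bud, Can-0 seedling and Col-0 floral bud) was higher. Lower in bud were 17 of 19 carbon fixation genes (median -1.43, or -0.90 with quantile normalization), as in RBCS1B (AT5G38430) (-2.89, adjusted p = 0.00216) and RCA (AT2G39730) (-1.88, adjusted p = 0.00264), and 8 of 13 photorespiration genes (median -1.11, or 12 and -1.60 median-centred), as in GLDT (AT1G11860) (-1.49, adjusted p = 0.00172). Aliphatic glucosinolate genes were lower in 15 of 20 cases (median -2.24), with CYP79F1 (-4.28, adjusted p = 0.00326) and MYB29 (-3.80, adjusted p = 0.000336). FMOGS-OX2 (AT1G62540) (2.42, adjusted p = 0.0346, and 0.0906 to 0.153 without 1 of Can-0 floral bud, Can-0 seedling and Col-0 seedling) and FMOGS-OX4 (1.39, adjusted p = 0.0160, and 0.0908 to 0.106 without 1 of Can-0 floral bud and Col-0 floral bud) were higher. The indole kind was lower in 10 of 13 (median -2.36), with MYB51 (-3.25, adjusted p = 0.00175) and CYP79B3 (AT2G22330) (-3.04, adjusted p = 0.00137). Salicylic acid genes were lower in 11 of 19 (median -1.60), among them PR1 (-6.26, adjusted p = 0.00124), and NLR receptors in 9 of 28 (median -0.43, or 15 and -0.92 median-centred and 17 and -0.94 with quantile normalization), as in RPS4 (AT5G45250) (-1.25, adjusted p = 0.00485, and 0.0531 without Can-0 floral bud). Camera gave adjusted p = 2.13e-21 for photosystem, 6.22e-12 for carbon fixation, 1.21e-07 for photorespiration, 7.26e-09 and 3.51e-08 for aliphatic and indole glucosinolates, 1.91e-07 for salicylic acid and 3.80e-06 for NLR genes. In the same order these were adjusted p = 0.467, 0.467, 0.467, 0.473, 0.473, 0.473 and 0.467 with an estimated correlation, and 37, 19, 9, 18, 10, 13 and 5 members passed adjusted over the list alone.

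Hormone, flowering and cold genes moved both ways or upward in bud. The vegetative storage protein gene VSP1 (AT5G24780) rose from 9.77 and 74.6 RPKM in seedling to 5708 and 6005 in bud (7.68 ± 0.88, adjusted p = 0.00398). The jasmonate synthesis genes AOC2 (AT3G25770) (-6.10, adjusted p = 0.00203) and AOS (AT5G42650) (-3.51, adjusted p = 0.00139) were lower, around a jasmonate median of 1.03 (0.54 median-centred; camera adjusted p = 0.786). The fruit regulator FUL (AT5G60910) (5.12, adjusted p = 0.000157) and the chromatin protein gene VIN3 (AT5G57380) (4.46, adjusted p = 0.000247) were higher. The repressors TEM2 (AT1G68840) (-4.49, adjusted p = 0.00513), TEM1 (AT1G25560) (-2.4, adjusted p = 0.00126), SNZ (-4.01, adjusted p = 0.000285), SVP (-2.42, adjusted p = 0.00572) and SMZ (-1.48, adjusted p = 0.00461) were lower. FLC (AT5G10140), a repressor removed by winter cold, was lower in bud (-2.12, adjusted p = 0.0465, and 0.133 to 0.227 without 1 of Can-0 floral bud, Col-0 floral bud and Col-0 seedling), as was its relative FLM (AT1G77080) (-1.34, adjusted p = 0.00640, and 0.0518 without Can-0 floral bud). The flowering time median of 0.10 turned to -0.37 with quantile normalization (camera adjusted p = 0.194). Of 12 cold and osmotic genes 8 were higher (median 2.27, or 5 and 1.78 median-centred; camera adjusted p = 0.130), including ERD10 (2.92, adjusted p = 0.00140). The suberin genes GPAT5 (AT3G11430) (6.18, adjusted p = 0.000158) and FAR1 (AT5G22500) (2.4, adjusted p = 0.00461) were higher in bud, although the endodermis list had a median of -0.02 (-0.51 median-centred), a mean of 0.37 and a downward rank (camera adjusted p = 0.288). IRT1 was higher (4.41, adjusted p = 0.000871) and the nicotianamine synthase NAS4 (AT1G56430) (-4.45, adjusted p = 0.00376) lower in an iron deficiency list with a median of -0.24 (-0.72 median-centred; camera adjusted p = 0.0471, adjusted p = 0.748 with an estimated correlation), which was 0.02 without Can-0 floral bud and 0.15 without Col-0 seedling.

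Ion transport and flavonoid genes moved both ways between bud and seedling, and camera called none of the lists given next. NRT1.5 (AT1G32450) (3.42, adjusted p = 0.00352) and NIP5;1 (AT4G10380) (2.37, adjusted p = 0.00420) were higher in bud. NRT1.1 (AT1G12110) (-2.27, adjusted p = 0.00459) and PHO1 (AT3G23430) (-1.18, adjusted p = 0.00350) were lower, around an ion transport median of 0.19 (-0.24 with quantile normalization; camera adjusted p = 0.786, downward). LDOX and DFR were lower (-4.21, adjusted p = 0.00564 and -4.04, adjusted p = 0.00445) and F3'H higher (3.86, adjusted p = 0.00591) around a flavonoid median of 0.70 (-0.03 with quantile normalization; camera adjusted p = 0.593, downward). The auxin importer AUX1 (AT2G38120) (1.92, adjusted p = 0.000792) was higher in a meristem list with a median of 0.25 (-0.23 median-centred; camera adjusted p = 0.914). The evening clock gene BOA (AT5G59570) (3.37, adjusted p = 0.00449) was higher (list median 0.50, or 0.01 median-centred; camera adjusted p = 0.860), and morning clock genes had a median of 1.07 (0.59 median-centred; camera adjusted p = 0.743). NSP1 was lower (-1.65, adjusted p = 0.000900) in a breakdown list with a median of 0.14 (-0.35 median-centred; camera adjusted p = 0.130). Medians were 0.00 for root hair (-0.48 median-centred), -0.08 for cell division and -0.20 for heat shock genes (camera adjusted p = 0.313, 0.133 and 0.130), the latter pair -0.56 and -0.69 median-centred, where 10 of 15 and 4 of 8 were lower against 2 and 1. Reference genes had a median of 0.32, or -0.16 median-centred (camera adjusted p = 0.860).

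By limma, 9336 genes differed between floral bud and seedling, 6837 higher and 2499 lower in bud, and 5290 of them by at least 1, with 6201 without Col-0 seedling, 2941 without Col-0 floral bud and 2859 without Can-0 floral bud. The median over all genes was 0.27, which quantile normalization moved by -0.42 to -0.15 and median-centring by -0.48 to -0.21, so that 3730 were higher and 5250 lower under the first and 3385 and 5522 under the second. Small differences in either direction therefore rest on the scaling.

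Floral buds against roots combined both contrasts. Green-tissue genes were higher in bud, with 37 of 37 photosystem genes (median 5.45), 18 of 19 carbon fixation genes (median 6.42) and 10 of 13 photorespiration genes (median 2.93). LHCB2.1 (AT2G05100), an antenna gene, stood at 417 and 238 RPKM in bud and 1.97 and 0.198 in root (7.39 ± 0.16, adjusted p = 7.21e-05). Higher in bud were 16 of 18 floral organ genes (median 4.95), with SEP3 at 252 and 274 RPKM and listed at 0 in both roots (8.04, adjusted p = 7.21e-05), and all 20 tested pollen genes (median 5.56), with AGP40 (AT3G20865) (7.61, adjusted p = 7.48e-05). The tapetum median of 3.11 was -0.06 without Col-0 floral bud, where members that reach 1 RPKM in bud alone were not tested. In the tapetum list GRP17 was higher (8.95, adjusted p = 0.000152) and TKPR1 (AT4G35420) (-1.63, adjusted p = 0.00530) lower. Lower in bud were 17 of 20 ion transport genes (median -2.79), all 11 root hair genes (median -3.16), 13 of 16 endodermis genes (median -4.71) and 14 of 18 iron deficiency genes (median -2.67). The potassium channel AKT1 (AT2G26650) (-5.71, adjusted p = 7.44e-05) and the suberin gene ASFT (AT5G41040) (-6.29, adjusted p = 8.21e-05) were among them, while the boron exporter BOR1 (AT2G47160) (1.34, adjusted p = 0.00112) and GPAT5 (2.44, adjusted p = 0.000637) were higher. Root meristem genes had a median of -2.14, with PIN2 lower (-4.53, adjusted p = 0.000158) and AUX1 higher (0.50, adjusted p = 0.0203, and 0.0562 to 0.144 without 1 of Can-0 floral bud, Can-0 root, Col-0 floral bud and Col-0 root).

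All 13 indole glucosinolate genes were lower in bud than root (median -3.35), with the regulator MYB34 at -5.07, adjusted p = 8.85e-05. Jasmonate genes were higher in 10 of 15 cases (median 2.07), with LOX2 at 9.41, adjusted p = 0.000229, and AOC2 was lower (-1.70, adjusted p = 0.0497, and 0.0620 to 0.256 without 1 of Can-0 floral bud, Can-0 root, Col-0 floral bud and Col-0 root). Heat shock genes were lower in 6 of 8 (median -0.83), with HSP70 at -4.21, adjusted p = 0.000860, and cell division genes in 8 of 15 (median -0.42, or 11 and -0.63 median-centred), with CDKB1;1 at -1.33, adjusted p = 0.00263. Morning clock genes were higher in 5 of 6 (median 2.12), with LHY (AT1G01060) (2.64, adjusted p = 0.00969). Reference genes were lower in 4 of 11 (median -0.43, or 9 and -0.64 median-centred). Camera called 17 lists here. Those higher in bud were photosystem (adjusted p = 3.12e-15), carbon fixation (adjusted p = 2.73e-09), photorespiration (adjusted p = 1.46e-05), floral organ identity (adjusted p = 1.72e-07), pollen (adjusted p = 2.45e-10), anther tapetum (adjusted p = 0.00667), jasmonate (adjusted p = 0.00667) and clock morning (adjusted p = 0.0413). Those lower in bud were root ion transport (adjusted p = 5.61e-06), root hair (adjusted p = 1.10e-05), endodermis and suberin (adjusted p = 3.39e-06), iron deficiency (adjusted p = 1.10e-05), root meristem (adjusted p = 0.0280), indole glucosinolate (adjusted p = 5.61e-06), heat shock (adjusted p = 0.0162), cell division (adjusted p = 0.0159) and reference genes (adjusted p = 0.0192). Each of these calls ended, at adjusted p = 0.413 to 0.611, with an estimated correlation. Adjusted over the list alone, the numbers passing were, in the same orders, 37, 18, 12, 16, 20, 10, 11 and 5, and 18, 11, 14, 15, 5, 13, 6, 7 and 4. No call was made for aliphatic glucosinolate (median -0.70, adjusted p = 0.160), glucosinolate breakdown (median 4.37, adjusted p = 0.458), flowering time (median 0.61, adjusted p = 0.358), NLR immune receptors (median 0.18, adjusted p = 0.617), salicylic acid defence (median -0.01, adjusted p = 0.876), cold and osmotic response (median 2.09, adjusted p = 0.0921), clock evening (median -0.31, adjusted p = 0.818), flavonoid and anthocyanin (median 1.00, adjusted p = 0.0624) and meiosis (median -0.43, adjusted p = 0.245). Of these the NLR median turned to -0.03 median-centred and the salicylic acid median to 0.01 with nuclear genes rescaled. Median-centred, the flowering time, evening clock, salicylic acid and meiosis medians were 0.40, -0.52, -0.22 and -0.64. In those lists TGG1 was higher in bud (9.56, adjusted p = 7.21e-05), as were FUL (5.82, adjusted p = 7.77e-05) and MYB111 (AT5G49330) (5.78, adjusted p = 7.88e-05), a flavonol regulator.

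By limma, 11932 genes differed between floral bud and root, 6309 higher and 5623 lower in bud, and 7886 of them by at least 1, with 7722 without Col-0 root, 6953 without Col-0 floral bud and 6584 without Can-0 floral bud. The median of 0.02 over all genes moved by -0.19 to -0.17 with quantile normalization and by -0.21 to -0.19 with median-centring, which gave 5447 higher and 7301 lower, and 5336 and 7488.

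**Figure D1:**
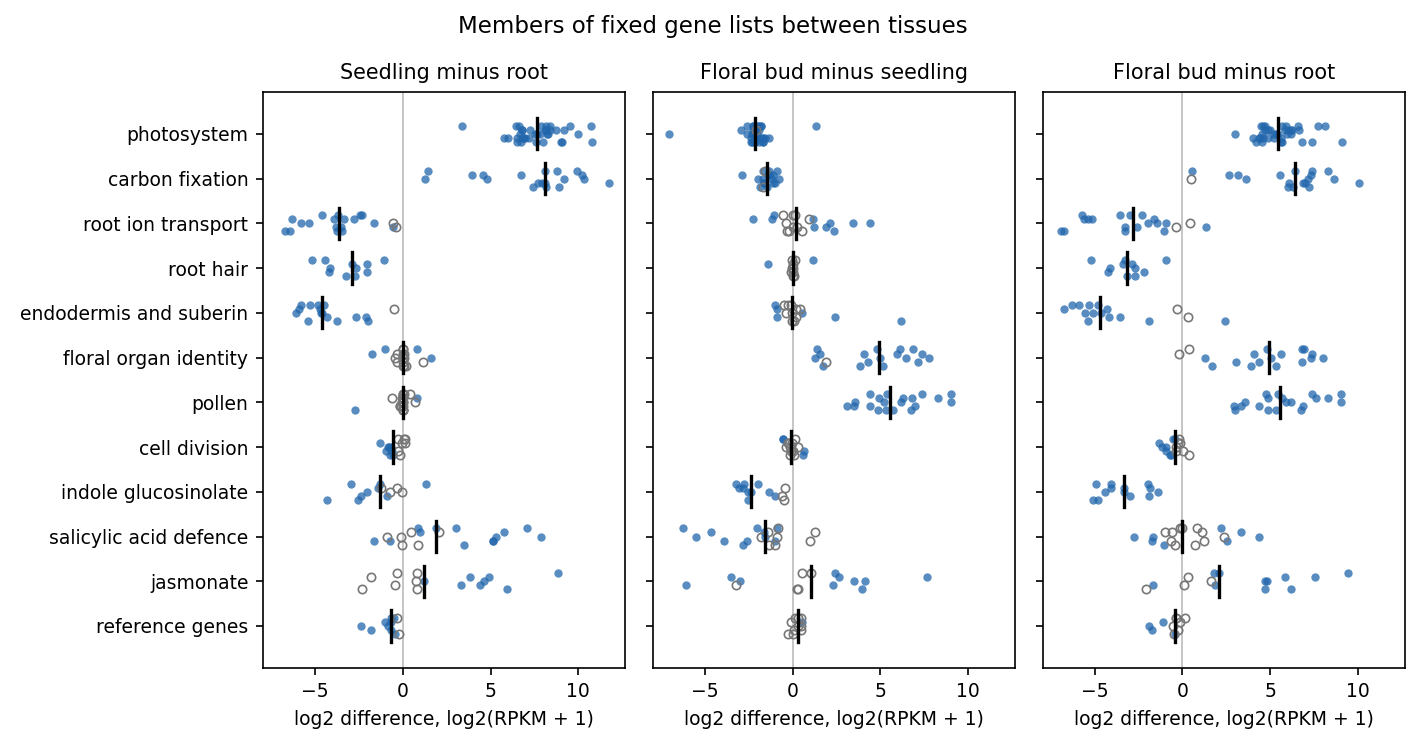
Difference in log2(RPKM + 1) of each tested member of 12 gene lists (horizontal axis) in the 3 comparisons between tissues, with members past adjusted p of 0.05 as filled blue points, other members as open grey points and each list's median as a black bar. Photosystem genes have medians of 7.63 in seedling minus root and -2.13 in floral bud minus seedling, and pollen genes have medians of 5.56 in both comparisons with floral bud.

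Some transcripts were found almost in a single tissue. In seedling these included LHCB1.4 at 1269 and 870.3 RPKM, AT3G05730 at 443 and 338, the peptide hormone gene RGF9 (AT5G64770) at 183 and 376, the growth regulator HBI1 (AT2G18300) at 55.1 and 39.6 and the glycine-rich GRP-3 (AT2G05520) at 611 and 1249. PR1 and PCC1 of the salicylic acid response also ranked there. AT3G16670 and AT1G31690, at 54.6 and 26.6 and 20.4 and 59.5 RPKM in seedling, were listed at 0 elsewhere. AT5G24210, at 26.0 and 159 RPKM, completed the first 10, with an adjusted p against bud of 0.00984, and 0.0527 to 0.0779 without 1 of Can-0 floral bud and Col-0 floral bud. In root the latex-like protein genes MLP329 (AT2G01530) and MLP34 (AT1G70850) stood at 748 and 983 and 812 and 1535 RPKM, the fatty-acid dioxygenase DOX1 (AT3G01420) at 882 and 653, the glucosidase BGLU22 (AT1G66280) at 362 and 652, the cell-wall gene GRP9 (AT2G05440) at 2091 and 505 and the dehydrogenase SDR4 (AT3G29250) at 307 and 402. AT1G52070, AT4G12545, AT5G26260 and AT5G37990 stood at 185 to 445 RPKM in root, and all 10 were at most 5.77 RPKM elsewhere. In floral bud PGA4 (AT1G02790), a pollen polygalacturonase, stood at 747 and 1146 RPKM and the pectin methylesterase VGDH2 (AT3G62170) at 907 and 599, both listed at 0 in the other tissues. AT3G01240 and AT3G49540 reached 1225 and 1004 and 1037 and 1068 RPKM in bud with at most 0.2 elsewhere, and AT5G61720, AT5G38760, AT3G07820, AT5G07410, AT3G07850 and AT3G14040 stood at 594 to 979.9 RPKM in bud. AT3G07850 and AT3G14040 are near-identical copies, and AT5G07410 is one of PPME1 (AT1G69940).

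By limma, with a difference of at least 2 over each of the other tissues, 205 genes were enriched in seedling, 1389 in root and 1235 in floral bud. The root count was 677 without Col-0 root and 753 without Can-0 root, and the bud count 410.0 without Col-0 floral bud and 372 without Can-0 floral bud. Genes that reached 1 RPKM only in the tissue of the missing library were not tested in those fits, so these counts also reflect the filter. With median-centred values 459 were enriched in seedling, and a pseudocount of 5 gave 109, 684 and 644.

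Between the accessions over all tissues, 3 of 21 flowering time genes and 1 of 20 aliphatic glucosinolate genes passed. The flowering repressor FLC stood at 4.85 and 104 RPKM in seedling, 0.124 and 106 in root and 0.123 and 27.8 in floral bud (5.14 ± 0.50, adjusted p = 0.0374), higher in Can-0. Its relative MAF3 (AT5G65060) was at 15.9, 13.6 and 21.3 RPKM in Col-0 seedling, root and bud and at most 0.147 in Can-0 (-4.01 ± 0.20, adjusted p = 0.0130). GS-OH (AT2G25450), an oxygenase that hydroxylates aliphatic glucosinolates, was at 172, 324 and 107 RPKM in Col-0 and 4.1, 0.793 and 1.41 in Can-0 (-6.02 ± 0.50, adjusted p = 0.0282). FRI, an activator of FLC, did not pass (0.46, adjusted p = 0.220), nor did the side-chain genes AOP3 (AT4G03050) (3.58, adjusted p = 0.0943), MAM1 (-1.30, adjusted p = 0.367) and MAM3 (0.61, adjusted p = 0.648). ESP, which turns glucosinolate breakdown toward nitriles, was at 13.5 and 2064 RPKM in seedling, 0 and 0.527 in root and 18.0 and 3221 in bud and did not pass over all tissues (5.05, adjusted p = 0.214). AOP2 was not analysed here. The FLC call also ended without Can-0 seedling (adjusted p = 0.0563).

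Several of the other genes with the largest differences were near 0 in all tissues of one accession. The polyubiquitin gene UBQ13 (AT1G65350) and AT5G03090 were listed at 0 in all Col-0 libraries and stood at 25.5, 74.2 and 28.8 RPKM, and 67.5, 108 and 49.3 RPKM, in Can-0 seedling, root and bud (5.28, adjusted p = 0.0168 and 6.17, adjusted p = 0.0110). Others higher in Can-0 were AT5G15360 (4.68), AT4G03156 (4.46), AT3G43572 (4.35), AT3G62460 (4.3), AT4G29760 (4.26), AT2G16490 (4.12) and AT4G32230 (4.0), at adjusted p = 0.0110 to 0.0194. The aquaporin gene PIP1;4 (AT4G00430) fell from 63.5, 32.3 and 68.1 RPKM in Col-0 to at most 0.0490 in Can-0 (-5.69, adjusted p = 0.0130). The asparaginyl-tRNA synthetase gene SYNC3 (AT1G70980) was lower in Can-0 too (-4.47, adjusted p = 0.0206), as were AT5G49440 (-5.47), AT2G14285 (-4.87), AT5G21020 (-4.85), AT2G14460 (-4.71), AT4G34881 (-4.68) and AT4G20480 (-3.84), at adjusted p = 0.0110 to 0.0156. AT4G34881 has a near-identical copy. AT2G16490 also had adjusted p of at least 0.0502 without either root library.

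Few list members passed. The NLR gene VICTL (AT5G46510) (-2.78, adjusted p = 0.0220, and 0.0544 to 0.137 without 1 of Can-0 floral bud, Can-0 seedling, Col-0 floral bud, Col-0 root and Col-0 seedling) and the cell-cycle activator CDC20.1 (AT4G33270) (-1.33, adjusted p = 0.0439, and 0.0906 to 0.162 without any 1 of the 6 libraries) were lower in Can-0, and both have near-identical copies. The NLR gene RPM1 (AT3G07040) was at 5.59, 1.85 and 2.65 RPKM in Col-0 and listed at 0 in Can-0, without passing (-2.03, adjusted p = 0.0712). As lists, camera placed photosystem (median -0.51, adjusted p = 2.78e-09), carbon fixation (median -0.44, adjusted p = 2.57e-05), cell division (median -0.23, adjusted p = 0.00834), photorespiration (median -0.23, adjusted p = 0.0153) and flowering time genes (median -0.34, adjusted p = 0.0153) lower in Can-0. It placed salicylic acid (median 0.63, adjusted p = 0.0203) and jasmonate genes (median 0.53, adjusted p = 0.0443) higher, although in root these lists were lower in Can-0, with medians of -0.37 (percentile 2.38) and -0.39 (percentile 0.780). All 7 calls had adjusted p = 0.920 with an estimated correlation. When adjusted over each list alone, the numbers passing were, in that order, 1, 0, 1, 1, 6, 0 and 0. Of the other 19 lists, the breakdown list had a median of 0.05 and a mean of -0.29 (camera adjusted p = 0.864), and all 19 lay at adjusted p = 0.0545 or above.

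By limma, 200 genes differed between Can-0 and Col-0 over the tissues at an adjusted p under 0.05, 84 higher and 116 lower in Can-0, and 3590 passed an unadjusted p of 0.05. No gene passed without Col-0 floral bud or without Can-0 floral bud (2202 and 2189 at an unadjusted p under 0.05), so every named call ended without either, at adjusted p = 0.125 to 0.194. A pseudocount of 5 gave 74, no filter 80, a mean of at least 5 RPKM 68 and no tissue block 16, and voom, chosen after the results were seen, gave 497. The count was 75, 91 and 64 without Col-0 seedling, Col-0 root and Can-0 seedling, 120 without Can-0 root, and 0 without the bud pair. The bud libraries came from different runs while those of seedling and root each shared a run.

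**Figure D2:**
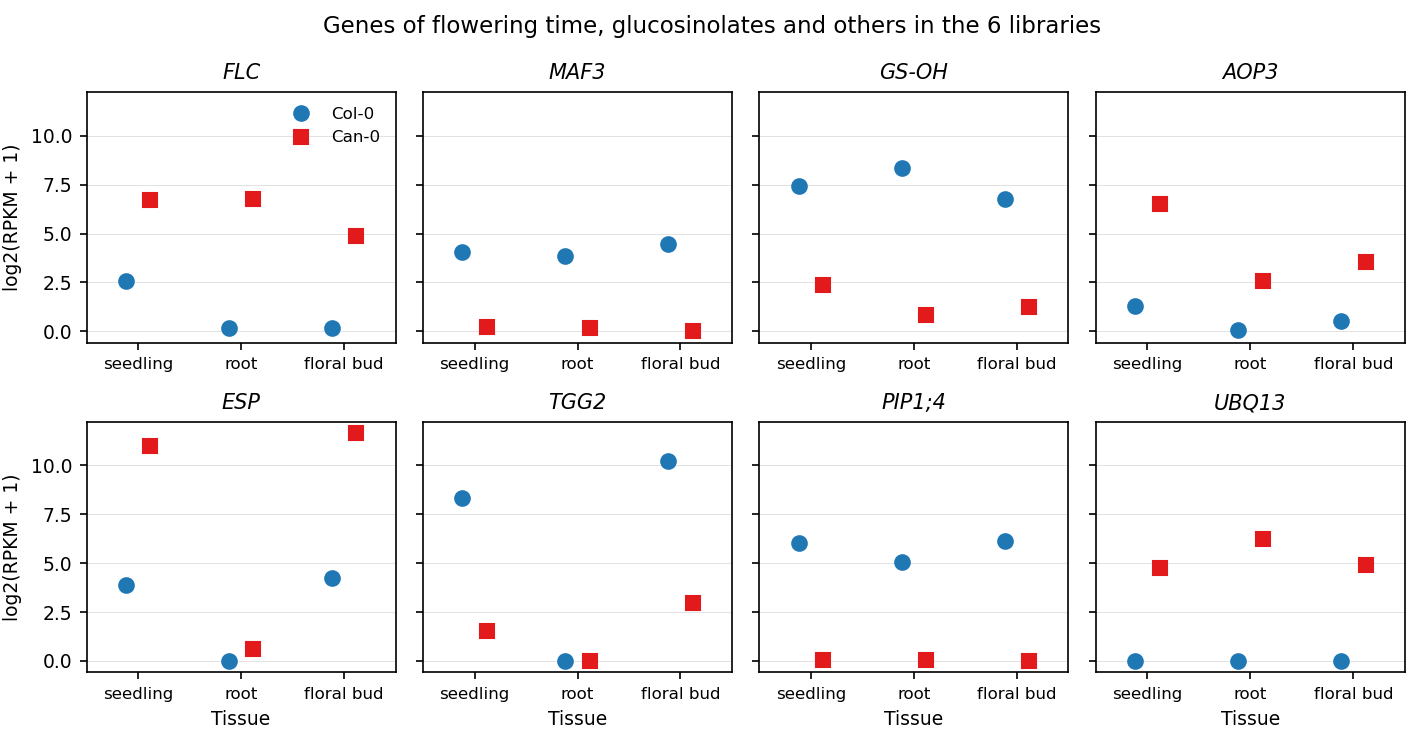
Expression of 8 genes as log2(RPKM + 1) (vertical axis) in seedling, root and floral bud, 1 library each, with Col-0 as blue circles and Can-0 as red squares. FLC is at 0.124 RPKM in Col-0 root and 106 in Can-0 root, and PIP1;4 is at 68.1 and 0 RPKM in floral bud.

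Within seedling, Can-0 showed more transcript of jasmonate, salicylic acid, evening clock and cold genes than Col-0. Values within a tissue come from single libraries and carry no test, so each list's median is given with its percentile among 10000 random lists matched on expression. The random lists were drawn gene by gene and do not copy how genes of a list vary together. Their central 95% is therefore too narrow for such lists, and extreme percentiles are a description only. The jasmonate median was 1.46 (percentile 100), with TAT3 (AT2G24850) at 2.21 and 35.9 RPKM, and the salicylic acid median was 1.1 (percentile 100), with PR5 (AT1G75040) at 15.2 and 93.0. Evening clock genes had a median of 1.33 (percentile 100) and morning clock genes of -1.68 (percentile 0), with ELF4 (AT2G40080) at 7.35 and 99.2 RPKM and PRR9 (AT2G46790) at 11.2 and 1.98. Aliphatic glucosinolate genes had a median of 0.40 (percentile 99.97), with AOP3 at 1.43 and 90.3 RPKM. Flowering time genes had a median of -0.65 (percentile 0), with the activator SOC1 (AT2G45660) at 25.1 and 1.95 RPKM. Photosystem, carbon fixation and flavonoid genes had medians of -0.28 (percentile 0.04), -0.40 (percentile 0.01) and -0.49 (percentile 0.04). The cold and osmotic median was 0.68 (percentile 99.98). Medians below the central 95% of random lists were also -0.36 (percentile 0.125) for photorespiration, -0.54 (percentile 0.4) for iron deficiency, -0.21 (percentile 1.01) for cell division and -0.11 (percentile 2.36) for NLR genes. ESP was at 13.5 and 2064 RPKM and the myrosinase TGG2 (AT5G25980) at 326 and 1.87. CYP71A13 (AT2G30770) of camalexin synthesis was at 0.758 and 71.2 RPKM, AT3G28320 at 0 and 38.3, the arginase gene ARGAH2 (AT4G08870) at 88.4 and 0.0315, AT1G66100 at 218 and 0, AT5G42530 at 169 and 0 and AT1G23130 at 301 and 3.56. A difference of at least 2 was met by 369 of 17766 genes, 194 higher and 175 lower in Can-0, and by 743 with a pseudocount of 0.1 and 110 with 5.

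Within root, Can-0 had less transcript of photosynthetic, flavonoid and cold genes and more of iron deficiency genes. Photosystem genes had a median of -0.87 (percentile 0), carbon fixation genes of -0.69 (percentile 0) and flavonoid genes of -2.16 (percentile 0), with the chalcone synthase gene CHS (AT5G13930) at 427 and 88.0 RPKM. LHCB1.3 was at 32.6 and 3.89 RPKM in root against 6380.4 and 4814 in seedling. Cold and osmotic genes had a median of -1.25 (percentile 0), with KIN1 (AT5G15960) at 145 and 26.0 RPKM, and root hair genes of -0.60 (percentile 0.01). Iron deficiency genes had a median of 0.46 (percentile 100), with the regulator BHLH38 (AT3G56970) at 7.07 and 36.7 RPKM. Other medians below the central 95% of random lists were -0.39 (percentile 0.780) for jasmonate, -0.37 (percentile 2.38) for salicylic acid, -0.49 (percentile 0) for indole glucosinolate, -0.71 (percentile 0.01) for flowering time, -0.27 (percentile 0.650) for NLR and -0.21 (percentile 2.07) for cell division genes. Adjacent genes of thalianol synthesis, a root triterpene pathway, were at 274, 162 and 353 RPKM in Col-0 and 0.243, 0.0647 and 0.0981 in Can-0 for THAS1 (AT5G48010), CYP708A2 (AT5G48000) and CYP705A5 (AT5G47990). AT5G26300 was at 1.22 and 305 RPKM, AT4G12170 at 1.91 and 242 and AT5G23830 at 105 and 0. A difference of at least 2 was met by 291 of 18573 genes, 112 higher and 179 lower in Can-0, and by 592 with a pseudocount of 0.1 and 89 with 5.

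Within floral bud, tapetum, pollen and salicylic acid genes had higher medians in Can-0, and cold genes a lower one. The tapetum median was 0.55 (percentile 99.99), with the pollen-coat lipase gene EXL4 (AT1G75910) at 1.08 and 41.4 RPKM, and the pollen median 0.33 (percentile 99.98), with the sugar transporter gene STP9 (AT1G50310) at 27.0 and 77.6. Salicylic acid genes had a median of 0.89 (percentile 100), with ACD6 (AT4G14400) at 0 and 9.87 RPKM. Cold and osmotic genes had a median of -0.72 (percentile 0), with RD29A (AT5G52310) at 254 and 57.2 RPKM. The clock medians were -0.52 for evening (percentile 0.0450) and 0.51 for morning genes (percentile 99.8). TGG2 was at 1207 and 6.76 RPKM, ESP at 18.0 and 3221 and ESM1 (AT3G14210), which favours isothiocyanates, at 23.0 and 0, and the breakdown list had a median of -0.44 (percentile 0.860). The thionin gene THI2.1 (AT1G72260) was at 397 and 1.15 RPKM, ARGAH2 at 145 and 0.155 and AT3G48640 at 0 and 35. A difference of at least 2 was met by 303 of 19174 genes, 142 higher and 161 lower in Can-0, and by 665 with a pseudocount of 0.1 and 86 with 5. Medians above the central 95% of random lists were also 0.52 (percentile 100) for aliphatic glucosinolate, 0.50 (percentile 99.9) for flavonoid, 0.27 (percentile 99.6) for jasmonate and 0.32 (percentile 98.2) for ion transport genes. Those below it were -0.31 (percentile 2.06) for photosystem, -0.50 (percentile 1.03) for indole glucosinolate and -0.17 (percentile 1.01) for flowering time genes. Heat shock, NLR and reference genes had medians of -0.03, -0.02 and -0.02.

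**Figure D3:**
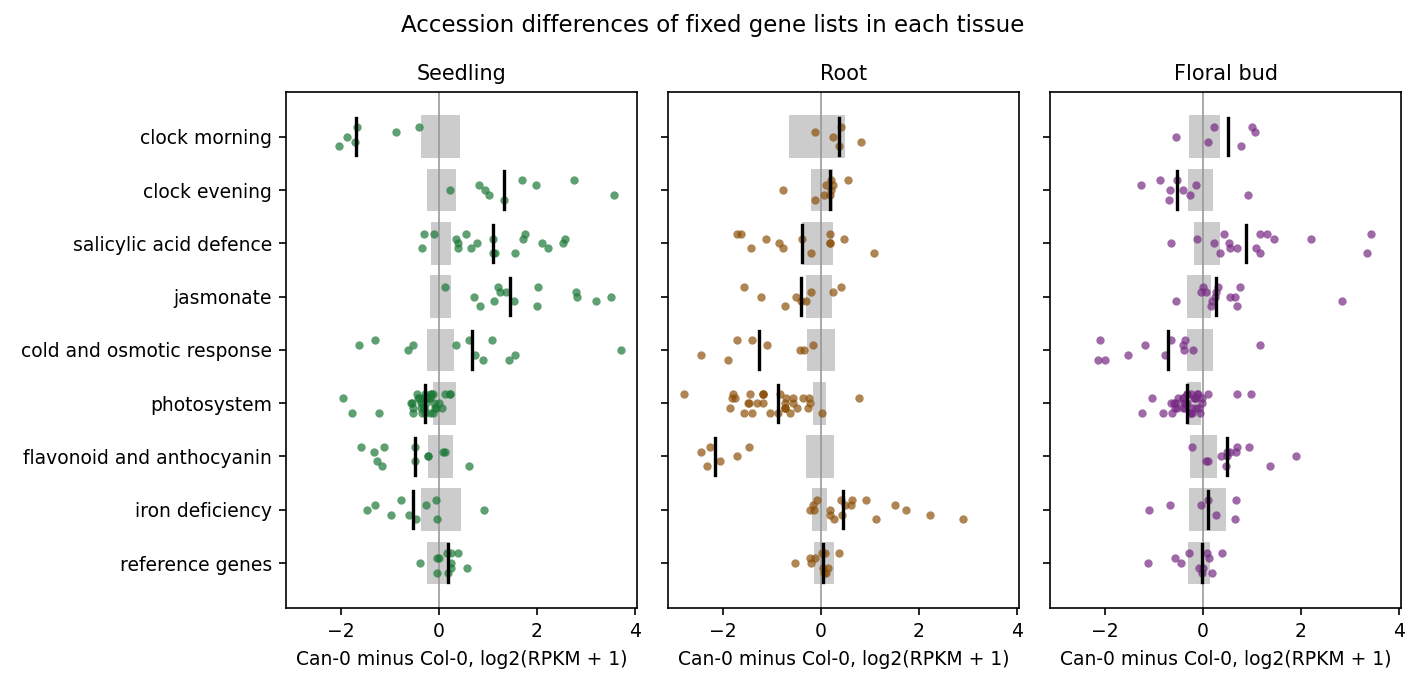
Can-0 minus Col-0 difference in log2(RPKM + 1) (horizontal axis) of the members of 9 gene lists within seedling, root and floral bud, 1 library per accession and tissue, with each list's median as a black bar and the central 95% of 10000 matched random lists as a grey band. Flavonoid genes have medians of -0.49, -2.16 and 0.50 in seedling, root and floral bud.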

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

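The rule behind these results, that a gene or list differ by at least 1 one way between the accessions in 1 tissue and by at least 1 the other way in another, was fixed with the comparisons, while the tests of a shared clock phase and of library scaling were chosen after the result was seen. The dawn-phased and dusk-phased lists were written once the clock genes had been seen to differ, before their own values were. Of 265 named genes and list members examined 16 met it, and no median of the 26 lists did. Each value comes from a single library per accession, and the differences between tissues were not tested. No group had the 4 libraries needed to look for an outlying one.

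The genes that met the rule include some of the cold and clock lists. The Can-0 minus Col-0 difference in log2(RPKM + 1) was 1.98 in seedling and -1.26 in floral bud for GRP7, 1.55 and -1.52 for COR15A, 1.08 and -2.09 for LTI30, and 1.43 and -2.13 for RD29A. It was 1.01 in floral bud and -1.66 in seedling for CCA1, and 1.17 and -1.62 for CBF2. For KIN1 it was 3.73 in seedling and -2.43 in root. Differences of opposite sign in seedling and root were 1.1 in seedling and -1.43 in root for FMO1, 1.14 and -1.12 for WRKY38, 2.00 and -1.23 for the jasmonate synthesis gene AOC3, and 1.03 and -1.18 for GRP-3. WRKY70 stood at 1.08 in floral bud and -1.71 in root, and CYP71A13 at 5.36 in seedling and -1.16 in floral bud. In flavonoid synthesis FLS1 stood at 1.39 in floral bud and -2.32 in root, and GSTF12 at 1.91 in floral bud and -1.16 in seedling. The iron regulator BHLH101 stood at 1.51 in root and -1.47 in seedling.

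Clock genes as a group went opposite ways, with Can-0 seedling high in evening and low in morning genes and Can-0 floral bud the reverse. A change in library scaling would move both groups alike, and the evening minus morning difference of medians in seedling was 3.01 against -0.46 to 0.56 in pairs of random lists (-1.03 in floral bud). A clock phase that differed between the accessions in the same way in all tissues would raise evening genes in bud as in seedling if both were harvested at the same hour. Their median in bud was -0.52, below the -0.30 to 0.22 of random lists. Harvest hours are not in the labels, so a shared phase difference stays open. Harvest at different times of day would move other daily genes as well, and genes outside the clock lists did. The median of dusk-phased genes exceeded that of dawn-phased genes by 2.80 in Can-0 seedling, against -0.52 to 0.44 in random pairs, and by -1.32 in floral bud. A difference in clock phase between the accessions would move these genes too, so they cannot tell it from harvest time. Different harvest times or a difference in clock phase may be behind the clock pattern in seedling and bud, and were not told apart. Cold genes had a median of -1.25 in root. There evening minus morning was -0.19, inside the -0.50 to 0.68 of random pairs. Dusk minus dawn was -0.342, at the lower edge of the -0.345 to 0.486 of random pairs. Whether harvest time was behind the cold genes in root therefore stays open. An accession difference that depends on tissue stays open and untested too.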

How the results depend on the processing

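Voom on approximate reads was the alternative added after the results were seen, and the others were fixed before. Pairing by replicate number was not possible because the groups share only replicate number 1. The tissue term already pairs the accessions within each tissue.

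Among called tissue results the direction turned only for MSH5 in floral bud minus seedling, which was -0.0919 with quantile normalization (adjusted p = 0.695, from 0.0170 to 0.695 over its alternatives), and for 3 medians of lists that camera called. The anther tapetum median in floral bud minus root was -0.0641 without Col-0 floral bud, the lowest, and 3.23 without Col-0 root, the highest. Without Col-0 floral bud the filter left out members that reach 1 RPKM in bud alone, so that median covers fewer members. In bud 14 tapetum members reached 1 RPKM in either accession, in seedling 3 and in root 4. Those that also turned were flavonoid genes in seedling minus root, -1.19 at a mean of at least 5 RPKM, and iron deficiency genes in floral bud minus seedling, 0.02 without Can-0 floral bud and 0.15 without Col-0 seedling, the highest, against -0.74 without Can-0 seedling, the lowest. Apart from the filter in the tapetum list, the cause was not tested. Among results without a call, 18 further list medians of 78 and 12 further named genes of 422 changed sign under some alternative, 10 of the medians with another scaling, and between the accessions 13 medians of 26 and 12 genes of 123 did. Of 388 named tissue calls 110 were lost under some alternative, 102 of them without 1 library. With quantile normalization 394 of 422 named tissue results kept their side of the threshold, with voom 400, with robust empirical Bayes 422, and without Can-0 floral bud 306 of 372. Leaving out a library leaves 1 arm with a single library, whose spread is then assumed to be that of the other groups.

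Requiring a difference of at least 1 left 7856 genes in seedling minus root, 5290 in floral bud minus seedling and 7886 in floral bud minus root by construction, and admitted 1065 seedling-enriched, 2821 root-enriched and 2194 floral bud-enriched genes by lowering their minimum from 2. Leaving out each library in turn gave 8068 to 11258 genes in seedling minus root, 2859 to 8997 in floral bud minus seedling and 6584 to 11799 in floral bud minus root, and 137 to 224 seedling-enriched, 677 to 1395 root-enriched and 372 to 1236 floral bud-enriched genes, with fewer libraries to estimate the spread. The filter was also applied again to the libraries left, so a gene that reached 1 RPKM only in the tissue of the missing library went untested. Without Col-0 floral bud 19618 genes were tested, without Can-0 floral bud 19599 and without Col-0 seedling 20644. Effects of the filter and of the spread on these counts were not separated. A pseudocount of 5 shrinks differences of weakly expressed genes and gave 109, 684 and 644 enriched genes in seedling, root and floral bud. With a mean of at least 5 RPKM, which tests 15330 genes, 910 were enriched in root and 803 in floral bud. Median-centred values gave 459 seedling-enriched genes, and the cause was not tested.

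For Can-0 minus Col-0 the main count of 200 became 74 with a pseudocount of 5, 80 with no filter, 68 with a mean of at least 5 RPKM, 16 with no tissue block and 497 with voom, and the cause was not tested apart from the block, without which tissue differences enter the spread. It was 75 without the seedling pair, 121 without the root pair and 0 without the floral bud pair, where limma left 2149 at an unadjusted p under 0.05. Leaving out single libraries gave 0 to 120, with 0 without Col-0 floral bud or Can-0 floral bud. All 22 named calls were lost without either, and the 20 largest then had adjusted p = 0.125 to 0.194. Quantile normalization, median-centring, rescaling nuclear genes and robust empirical Bayes gave 219, 206, 208 and 189.

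Within tissues, where the rule is a fold without a test, a pseudocount of 0.1 gave 743, 592 and 665 genes in seedling, root and floral bud and a pseudocount of 5 gave 110, 89 and 86, as the added value sets the fold of weakly expressed genes. A mean of at least 5 RPKM gave 179 in root and 183 in floral bud, from fewer genes. Camera called 16, 11, 17 and 7 lists in seedling minus root, floral bud minus seedling, floral bud minus root and Can-0 minus Col-0, and 0 in each with an estimated correlation. The estimated correlation and its test rest on the 2 residual degrees of freedom of the fit, which leaves little power. Even photosystem, with 37 of 37 genes higher in seedling than root, had camera adjusted p = 0.376 there. A gene of 1 kb under 0.131 to 0.138 RPKM, the worth of 3 reads in each library, cannot be told from absent.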

Other observations

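Several tests were chosen after the result was seen. They are those of genes near-absent in Col-0, of tissue with the makeup of the seedling libraries, of the flavonoid ratio and of other splits. The 5 added lists were written after the main tests had been seen. Those of camalexin and root triterpenes were written around CYP71A13, THAS1, CYP708A2 and CYP705A5, whose values were known.

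Synthesis genes of camalexin, an indole phytoalexin, were higher in Can-0 seedling. CYP71A13 stood at 0.758 and 71.2 RPKM, PAD3 at 1.49 and 47.8, CYP71A12 at 0.891 and 8.21 and GGP1 at 188 and 416 in Col-0 and Can-0, while in root, where the list's median of -0.12 lay inside random lists, CYP71A12 stood at 22.3 and 2.12, PAD3 at 40.9 and 37.5 and GGP1 at 269 and 330.1. Root triterpene genes had no common direction, with a median of -0.09 inside the -0.27 to 0.18 of random lists. Of the thalianol cluster AT5G47980 stood at 45.6 and 7.06 and AT5G47950 at 21.8 and 5.16 RPKM beside the near-absent CYP708A2 and CYP705A5, whereas the marneral genes MRN1, CYP71A16 and CYP705A12 stood at 34.7 and 74.1, 52.7 and 116 and 38.7 and 87.5. PEN1 stood at 8.74 and 8.13, CYP705A1 at 8.51 and 27.4 and BARS1 at 0.0775 and 1.23. The dusk-phased cold gene COR27 stood at 2.12 and 63.0 RPKM in seedling, 42.9 and 11.0 in root and 145 and 33.2 in floral bud.

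A set of 108 genes reached at least 5 RPKM in one accession and at most 0.2 in every tissue of the other, 67 near-absent in Can-0 and 41 in Col-0. Near-identical copies could take up such reads, but 8.33% of the genes (9 of 108, Wilson 95% interval 4.45% to 15.1%) had one. If Can-0 reads were lost against Col-0 gene models, most would be near-absent in Can-0, and 62.0% were (52.6% to 70.6%), though loss of genes from Can-0 would give the same share, and the 41 genes near-absent in Col-0 cannot arise that way. Genes lost or silenced together might lie side by side, and 7 next-door pairs were near-absent in the same accession, against at most 3 in random sets of expressed genes (mean 0.235, central 95% up to 1), among them CYP705A5 and CYP708A2, PP2-A8 and PP2-A6, and in Col-0 AT5G47260 and ADR1-L3. Lost reads and lost or silenced genes both stay open for the Can-0 set. All 41 genes near-absent in Col-0 are in the reference, which is the Col-0 genome. That argues against gene loss for those 41, and silencing in Col-0 was not tested.

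Photosystem and flavonoid genes were lower in Can-0 root than in Col-0 root, by medians of -0.87 and -2.16, and less so in Can-0 seedling, by -0.28 and -0.49 (percentile 0.04 each), while in floral bud the medians were -0.31 (percentile 2.06) and 0.50 (percentile 99.9), so neither a cause in the root libraries alone nor a shift shared by all tissues covers both lists. Shoot tissue in the Col-0 root library could raise the first. Outside the photosystem, carbon fixation and photorespiration lists, 71 abundant seedling-enriched transcripts stood there at a median of 1.16% of their seedling level (0.544% to 3.13%). That is above the 0.315% that the photosystem excess needs, and leaves it open because roots may express those genes themselves. The 71 still include photosynthetic genes such as PSAH2 (0.155%) and PETE1 (0.416%), so they are not independent of the pattern. Tissue with the makeup of the seedling libraries would bring all 71. Yet 25.4% of the 71 (18 of 71, Wilson interval 16.7% to 36.6%) stood at less than 50% of the percent needed, among them CA2 and PSAH2. Part of a shoot such as the hypocotyl therefore stays open, but not tissue of that makeup. Shoot tissue would not explain the flavonoid genes, which stood in Col-0 root at a median of 7.27 times Col-0 seedling, above 1 in 6 of 6. More light at the Col-0 roots may have acted on both in root. There 14 light-response genes had a median of -0.87 in Can-0 minus Col-0, below the -0.27 to 0.17 of random lists. Of these 12 were lower and 2, HY5 and BBX22, higher. Several are far more abundant in shoots, as PORB at 650 RPKM in Col-0 seedling and 6.71 in Col-0 root. Shoot tissue would raise those in Col-0 root too, so the list cannot tell light from shoot tissue. The list was lower in soil-grown Can-0 seedling as well (-0.62 against -0.20 to 0.24), while floral bud went the other way (0.20 against -0.21 to 0.18). An accession difference in light response that depends on tissue therefore stays open and untested beside more light. Dawn-phased genes had the same signs in seedling (-0.89) and floral bud (0.25), but not in root (0.15). Harvest time or clock phase therefore also stays open for the light-response list in seedling and bud, and was not tested there.

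For the accession count, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 200 genes, the highest other split 0, and 1 split in 10 reached the real count. Every other split leaves accession differences in the spread, and several put both libraries of a tissue on the same side. Low counts there were therefore largely set in advance, and no conclusion is drawn from them.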
